A study of Mus musculus with 9 samples.

How the data were processed

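Expression was measured in mouse primary myoblasts derived from satellite cells, in 9 samples of 3 groups (control, BMP4 and GREM1, 3 each), on 1 Affymetrix array per sample. The deposited table holds log2 expression values that the authors made by robust multi-array average (RMA) in Affymetrix Expression Console, per the submitters' processing notes, which corrects background, normalizes between arrays and summarises each gene-level probe set. The array model, the chip definition and the genome build are not given in the sources used here. The values ran from 1.80 to 12.7, with array medians between 5.00 and 5.12, and were used as deposited. For arrays the number of arrays limits the precision. The labels do not say whether the replicates are separate cultures, so the p-values measure the spread between these samples.

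Of 24973 probe sets, 24015 had 1 gene symbol and 958 had none here. The latter were left out of the comparisons and are reported in the closing part. Symbols were checked against the Entrez gene table, in which 23922 named probe sets were found and 93 were not, and 0 symbols needed an update. For 4 genes with more than 1 probe set the probe set with the highest mean over the 9 arrays was taken, which left 24011 genes. A gene was tested if at least 3 arrays lay above the 30th percentile of their own named probe sets (3.89 to 4.02 on the log2 scale), which kept 17141 genes and left out 6870.

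Differences between groups were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on all 9 arrays together, with 6 residual degrees of freedom and a prior of 3.47 degrees of freedom. The comparisons were BMP4 with control, GREM1 with control and BMP4 with GREM1, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The median SE of a difference was 0.115. All values against control share the same 3 control arrays. A gene is called higher or lower, risen or fallen, only where it passed this test, and elsewhere values are given. With 3 arrays against 3, chance gives 10% of genes whose groups do not overlap.

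Shifts of 32 gene lists, written down with their members, were tested with camera, which compares a list with the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Camera with the correlation estimated from the data, and fry, which tests whether the members of a list move in one direction without comparing them with other genes, were alternatives. The lists cover BMP-SMAD target genes, BMP ligands and antagonists, BMP receptors and SMADs, TGF-beta targets, satellite cell identity, myogenic differentiation, sarcomere, excitation-contraction coupling and neuromuscular junction, myoblast fusion, DNA replication, mitosis, cell cycle inhibition, Notch, Wnt, osteoblasts, cartilage, adipogenesis, fibroblasts, pericytes, endothelium, leukocytes, Schwann cells and tendon, immediate early genes, interferon, NF-kB, the unfolded protein response, hypoxia, p53, atrophy, extracellular matrix, ribosomal proteins and oxidative phosphorylation. Counts of members past the threshold are given over all genes and adjusted over the list alone.

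Genes named in the text follow a rule. Among genes past the threshold whose groups did not overlap, the 10 with the largest rise and the 10 with the largest fall in each comparison were named, or all that passed where fewer did, skipping predicted genes and clones. Up to 4 members of each list with the smallest unadjusted p were named too, and Bmp4, Grem1, Id1, Id3, Smad6, Myod1, Myog and Pax7 in every comparison. The comparisons, the filter, the lists, this rule and the alternatives were fixed before the data were examined. Tmem119, Htra3, Pdgfc, Il13ra1, Fam135a and Gm20758 after BMP4, Rbm38, Ncam1, Cxcr4, Ier3 and Klf10 after GREM1, and Nog and Bmper between BMP4 and GREM1 fall outside the rule and were chosen after their values were seen.

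The changes after BMP4 and after GREM1 were compared across genes by Pearson's r, Spearman's rho, the covariance, the share of genes with the same sign and the overlap of called genes. As both share controls, the same measures were computed on 100 simulated data sets of unchanged groups with shared controls and the spread within groups, on 100 with the spread left after the replicate block, and the overlap of calls on 20. The simulations with the spread after the block, and the signs of genes called for GREM1 without 1 control and measured from that control, were added after seeing the data.

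The alternatives were the replicate number of the labels as a block, a fit of only the groups compared, an intensity trend in the variance prior, array weights, quantile normalization once more, centring on array medians, no filter and a stricter one at the 50th percentile, the mean of a gene's probe sets, each probe set tested separately, and leaving out each array in turn. Values of arrays with the same replicate number correlated after their group means were removed, with coefficients from 0.0884 to 0.580, and 8 of 9 arrays correlated best with an array of their own number. The labels do not state what the number stands for. Where the block changed a call against control of a list, or of a gene whose value in that comparison is given, its value stands beside the result. The block and an estimated correlation together were added after seeing the data.

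The method was tested on simulated data with the spread of these arrays. Of genes changed by 0.5, 1 and 2 on the log2 scale it recovered 40%, 82.7% and 97.1% in the comparison of BMP4 with control, 33.3%, 85.7% and 98.3% in that of GREM1 with control and 33.3%, 80.6% and 97.2% in that of BMP4 with GREM1, and it called 8, 10 and 7 unchanged genes. For BMP4 with control these were 22 of 55, 62 of 75 and 68 of 70 changed genes, where 20 genes passed in the data. With fewer changed genes the adjustment is stricter, so recovery in that comparison may be lower. Camera called a list in 0 of 20 unchanged simulated data sets, and called a list shifted by 0.4 in 20 of 20. Simulated genes were drawn independently of each other, so this does not test false calls of lists whose members vary together. Figures were drawn with matplotlib 3.10.9.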

Results

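Gene expression was measured on 9 Affymetrix arrays of mouse primary myoblasts, the proliferating progeny of satellite cells, which are the stem cells of skeletal muscle. Per the labels, cells grown with 20% fetal bovine serum were moved to 2% horse serum, a low-serum condition in which myoblasts leave the cell cycle and form muscle fibres, and RNA was taken after 24 h. BMP4 was given at 100 ng/ml and GREM1 at 500 ng/ml, and the controls were mock-treated, with 3 arrays in each group. BMP4 is a secreted signal that acts through BMP receptors and SMAD transcription factors, and GREM1 is a secreted antagonist that binds BMP ligands and keeps them from their receptors. After dim genes were left out, 17141 genes were tested, and differences are given as log2 values with their standard error (SE) from limma. Array medians lay between 5.00 and 5.12 on the log2 scale, and the number of arrays limits the precision. The first principal component, with 42.3% of the variance, parted the GREM1 arrays, at 16.0 to 27.5, from the other arrays, all below 0. The second, with 20.9%, set control replicate 1 apart at 31.6, the next highest array being BMP4 replicate 1 at 6.12.

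The comparison of BMP4 with control asks which genes answer added BMP4. The largest rises were in Fabp7, a fatty acid binding protein, by 2.36 ± 0.11 (5.12-fold, adjusted p = 2.66e-05), and in Sp7, a transcription factor of osteoblast formation, by 1.98 ± 0.10 (3.95-fold, adjusted p = 2.66e-05). Sp7 went from 7.13 ± 0.054 (SD) in the controls to 9.11 ± 0.15 with BMP4. Smad7, an inhibitory SMAD that BMP signalling induces, rose by 1.18 ± 0.13, Ptgs2, the inducible cyclooxygenase, by 1.27 ± 0.13, Lgr6, a receptor for R-spondins, by 1.17 ± 0.12 and Car8, a carbonic anhydrase-related protein, by 1.13 ± 0.14 (the largest adjusted p = 0.0191). The collagen prolyl hydroxylase subunit P4ha3 (0.95), the adhesion receptor Adgrg3 (0.94), the lymphatic growth factor Vegfc (0.92) and Whrn (0.92) also rose, and the integrin subunit Itga3, Trp53i11 and Fgf9, a fibroblast growth factor, fell by 0.81, 0.77 and 0.66. The other genes past the test were Tmem119 (0.87), Htra3 (0.80), Pdgfc (0.74), Il13ra1 (0.70), Fam135a (0.54), Btg2 and the predicted gene Gm20758 (-0.85). In all, 20 genes passed, 16 higher and 4 lower with BMP4, and 6 of them rose at least 2-fold. Every one of the 20 had BMP4 arrays that did not overlap the controls, as did 11.2% of all tested genes, where chance gives 10%.

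BMP-SMAD target genes, a list of 23 measured members, had a median of 0.37 with BMP4. Smad7 rose, and the other 22 did not pass over all genes, while 10 rose when adjusted over the list alone and 3 rose over all genes with the replicate block. The list stood above the other genes (camera, adjusted p = 3.51e-13, and adjusted p = 0.0708 with an estimated correlation). Smad6, the other inhibitory SMAD, was 1.03 (adjusted p = 0.0796), Hey1 0.48 (adjusted p = 0.140) and Dlx3 0.60 (adjusted p = 0.193, or 0.0441 with the replicate number as a block). Id1 and Id3, inhibitors of myogenic transcription factors, were 0.52 ± 0.21 and 0.99 ± 0.41 and did not pass (adjusted p = 0.600 and 0.600). Among BMP ligands and antagonists, 0 of 24 passed in limma (1 rose when adjusted over the list alone, and 2 were higher and 1 lower at an unadjusted p under 0.05), with a list median of 0.10 (adjusted p = 0.162). The BMP-binding membrane protein Crim1 was 0.78 (adjusted p = 0.0504, or 0.0138 with the block). The Bmp4 transcript itself lay below the filter in the controls, at 3.87 ± 0.17 (SD), and the Grem1 transcript differed by 0.036 ± 0.12 (adjusted p = 0.954).

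The medians of 3 other lists were above 0 with BMP4 and passed camera at the preset correlation. TGF-beta target genes had a median of 0.22 (18 measured, adjusted p = 0.0118, and adjusted p = 0.323 with an estimated correlation). In limma 0 passed singly over all genes, where 5 were higher and 1 lower at an unadjusted p under 0.05, and over the list alone 3 rose and 1 fell. The collagen cross-linking enzyme Lox was 0.40, Tgfb1 0.88 and the matrix protein Tnc -0.44 (adjusted p = 0.0864, 0.265 and 0.183). Cell cycle inhibitors and quiescence genes had a median of 0.11 (22 measured, adjusted p = 0.0217, and adjusted p = 0.323 with an estimated correlation). The antiproliferative gene Btg2 rose by 0.86 ± 0.12 (adjusted p = 0.0331), 2 members rose over the list alone and 2 with the block, and Gas6 was 0.74 (adjusted p = 0.295, or 0.0138 with the block). Unfolded protein response genes had a median of 0.12 (22 measured, adjusted p = 0.0182, and adjusted p = 0.620 with an estimated correlation). In limma 0 members passed over all genes or over the list alone, with 1 higher at an unadjusted p under 0.05, and the chaperone Hspa5 was 0.46 (adjusted p = 0.658). In fry the TGF-beta and unfolded protein response lists did not pass (adjusted p = 0.0856 and 0.414). Control replicate 1 had the lowest Id3 and Hspa5 of the controls. Without it the adjusted p of the TGF-beta, cell cycle inhibitor and unfolded protein response lists was 0.128, 0.0656 and 0.292, and that of the cell cycle inhibitors was 0.0787 without control replicate 3. The 3 medians were 0.10, 0.058 and 0.052 without control replicate 1, and that of the cell cycle inhibitors was 0.055 without BMP4 replicate 3.

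The muscle and proliferation programmes moved little with BMP4. Medians were 0.016 over 25 myogenic differentiation factors, 0.023 over 40 sarcomere genes, 0.032 over 24 excitation-contraction and neuromuscular junction genes, 0.070 over 33 DNA replication and G1/S genes and 0.11 over 37 mitosis genes. In these lists 0 genes passed in limma, over all genes or over the list alone, and 0, 1, 1, 2 and 0 had an unadjusted p under 0.05. Of the lists, mitosis genes alone crossed the threshold with the replicate block (camera, adjusted p = 0.155 without it, 0.00630 with it, and adjusted p = 0.647 with it and an estimated correlation). Myod1, Myog and Pax7, which mark committed, differentiating and stem-like myogenic cells, were 0.42 ± 0.17, 0.32 ± 0.27 and 0.15 ± 0.15 and did not pass. The heparan sulfate proteoglycan Sdc3 was 0.56 (adjusted p = 0.0504, or 0.0339 with the block) and the chemokine Cxcl12 0.76 (adjusted p = 0.520, or 0.0135 with the block). With the block 65 genes passed, 52 higher and 13 lower, all 20 among them. The count of 20 was 2, 3 and 2 without control replicates 1, 2 and 3, 10, 4 and 13 without BMP4 replicates 1, 2 and 3, and 12, 12 and 17 without GREM1 replicates 1, 2 and 3. Of the 20 genes 18, 17 and 18 lost the call without those controls, 12, 16 and 11 without the BMP4 arrays and 8, 8 and 6 without the GREM1 arrays, and Fabp7 and Sp7 kept theirs under every alternative.

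**Figure D1:**
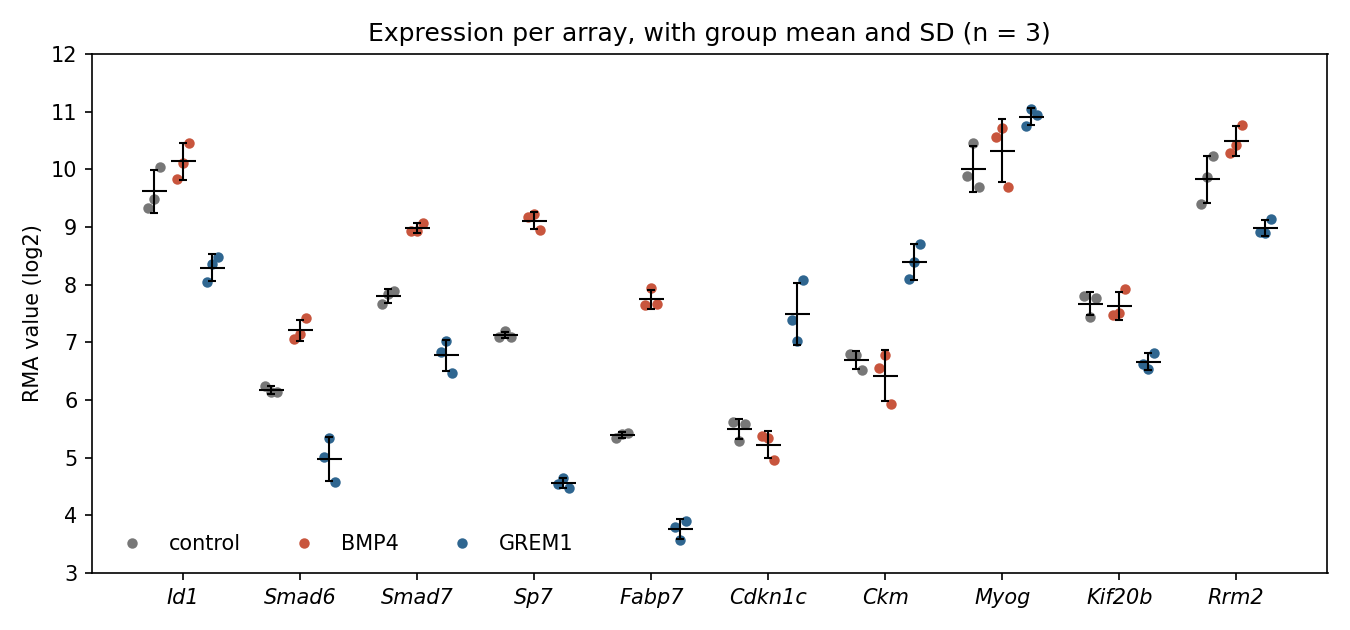
Expression per array for 10 genes, on the log2 scale, in control (grey), BMP4 (red) and GREM1 (blue) arrays; points are single arrays and bars the group mean with its SD (n = 3). Sp7 and Fabp7 lie above the controls with BMP4 and below them with GREM1, while Cdkn1c and Ckm are higher and Kif20b is lower with GREM1.

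The comparison of GREM1 with control asks what changes when the antagonist is added to myoblasts under the same conditions. The lists of BMP-SMAD targets, mitosis and replication genes had medians below 0 and those of muscle differentiation genes above 0. Sct, which encodes the hormone secretin, changed by -2.80 ± 0.33 (adjusted p = 0.00315) and Sp7 by -2.57 ± 0.10 (5.96-fold lower, adjusted p = 4.63e-06). Selp, the adhesion molecule P-selectin, changed by -2.57 ± 0.21 and Kctd12, an auxiliary subunit of GABA-B receptors, by -2.41 ± 0.19 (both adjusted p = 5.42e-04). Lgr6, the homeobox gene Prrx2, Fabp7, Car8, Has2os and Ifi204 fell by 1.94, 1.92, 1.64, 1.59, 1.53 and 1.53, although Ifi204 (adjusted p = 0.0492) lost the call without any one control or GREM1 array or BMP4 replicate 2 (highest adjusted p = 0.169 over the alternatives). The largest rises were in Ctrb1, a chymotrypsinogen, by 2.02 ± 0.16, Cdkn1c, the cyclin-dependent kinase inhibitor p57, by 2.00 ± 0.24 (3.99-fold, adjusted p = 0.00321) and Spry1, an inhibitor of receptor tyrosine kinase signalling, by 1.94 ± 0.16 (adjusted p = 5.42e-04). The adhesion receptor Adgrg1 (1.71), the muscle creatine kinase Ckm (1.70), mesothelin, Msln (1.69), the muscle ubiquitin ligase subunit Asb2 (1.67), the phosphodiesterase Pde2a (1.61), Dnase1l3 (1.54) and Cyria (1.49) followed.

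In all, 735 genes passed, 356 higher and 379 lower with GREM1, and 113 changed at least 2-fold, 51 up and 62 down. All 735 had arrays that did not overlap the controls, as did 24.0% of tested genes against 10% by chance. With arrays centred on their medians, 453 genes were higher and 317 lower. With the block 1985 genes passed, 956 higher and 1029 lower, with all 735 among them. The count was 307 and 267 without control replicates 1 and 3, 486 without BMP4 replicate 2, and 248, 245 and 482 without GREM1 replicates 1, 2 and 3. Of the 88 genes named in the text that passed, 49 kept the call under every alternative. The call was lost by 30, 13 and 34 of them without control replicates 1, 2 and 3, by 9, 15 and 4 without BMP4 replicates 1, 2 and 3, and by 37, 34 and 22 without GREM1 replicates 1, 2 and 3. Those that lost it whichever GREM1 array was left out were Acta2, Atp2a1, Car3, Ccn4, Cd14, Dysf, Gas1, Hes1, Ifi203-ps, Ifi204, Mmp2, Mymx, Ncam1, Nfkbia, P4ha1, Rbm38, Tagln, Thbs1, Tnfaip3 and Unc45b, and whichever control was left out Ccn4, Fstl1, Gas1, Hes1, Ier3, Ifi204, Mmp2, Nfkbia, Rgmb, Tagln and Thbs1.

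BMP-SMAD target genes had a median of -0.37, and 8 of the 23 measured members fell (12 adjusted over the list alone). Prrx2, Smad6 (-1.20 ± 0.18, adjusted p = 0.00784), Smad7 (-1.03 ± 0.13), the homeobox gene Dlx2 (-0.99) and Hey1 (-0.77) fell, as did Id1 (-1.32 ± 0.21, adjusted p = 0.0117, and 0.0556 without GREM1 replicate 1). Id3 was -0.81 ± 0.41 (adjusted p = 0.307, or 0.0251 with the block). The list shift passed camera with adjusted p = 3.14e-09, and had adjusted p = 0.190 with an estimated correlation. The Grem1 transcript fell by 0.79 (adjusted p = 0.00887) in cells given the protein. With Crim1 (-0.85) and Fstl1 (-0.82) it made up the 3 of 24 BMP ligands and antagonists that fell (4 over the list alone, and 1 rise with 6 falls with the block), a list whose median of -0.077 did not pass (adjusted p = 0.163). Of 19 BMP receptors and SMADs, 3 rose (3 over the list alone): Smad3 (1.00), which relays TGF-beta signals, and the BMP co-receptors Rgma (1.01) and Rgmb (0.45).

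All 37 mitosis and 33 DNA replication and G1/S genes had negative values after GREM1. Of 37 mitosis genes 11 fell (34 adjusted over the list alone, 35 with the block), with a median of -0.67. The kinesin Kif20b fell by 1.01 (adjusted p = 0.00747), and Gtse1, Nusap1 and the kinase Aurkb by 0.67, 0.75 and 0.65. Of 33 DNA replication and G1/S genes 9 fell (18 over the list alone, 19 with the block), with a median of -0.44, among them thymidylate synthase, Tyms, by 0.99 (adjusted p = 0.00784), the polymerase subunit Pole by 0.81, the replication licensing factor Cdc6 by 0.61 and Dscc1 by 0.72. In camera the adjusted p was 1.27e-17 for mitosis and 3.96e-11 for replication genes, and adjusted p = 0.374 with an estimated correlation for both, and neither passed fry (adjusted p = 0.0621 for both). Among 22 cell cycle inhibitors and quiescence genes Cdkn1c, Spry1 and Gas1 (0.33) rose and Hes1 fell by 0.40 (4 and 1 over the list alone, 4 and 3 with the block), with a median of 0.10 (adjusted p = 0.0508).

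The lists of muscle differentiation genes had medians above 0. Of 25 myogenic differentiation factors 5 rose (11 rose and 1 fell over the list alone, 13 rose with the block), with a median of 0.45. They were Cdkn1c, the transcription factors Mef2a (0.87 ± 0.12), Mef2d (0.88) and Srf (0.47), and the RNA-binding protein Rbm38 (0.60). Of 40 sarcomere and contractile genes 2 rose (2 over the list alone, 13 with the block), Ckm and the myosin chaperone Unc45b (1.20), with a median of 0.33 (0.21 without control replicate 3) and 38 members above 0. Actn3 was 0.63 (adjusted p = 0.1, or 0.00742 with the block). Of 24 excitation-contraction and neuromuscular junction genes 2 rose (10 over the list alone, 14 with the block), the acetylcholine receptor subunit Chrng (0.67) and the calcium pump Atp2a1 (0.85), with a median of 0.39. Chrnd was 0.53 (adjusted p = 0.0510, or 0.00730 with the block) and Jph2 0.31 (adjusted p = 0.0726, or 0.0466 with the block). The 3 lists passed camera (adjusted p = 1.75e-08, 1.18e-07 and 1.18e-07), and had adjusted p = 0.374, 0.508 and 0.374 with an estimated correlation. In fry the differentiation factors passed (adjusted p = 0.0456), and the sarcomere and excitation-contraction genes did not (adjusted p = 0.225 and 0.0837). Myog was 0.90 ± 0.27 (adjusted p = 0.0946, or 0.0167 with the block), and Myod1 (0.27 ± 0.17) and Pax7 (-0.20 ± 0.15) did not pass. Of 21 myoblast fusion genes 2 rose (2 over the list alone, 5 with 1 fall with the block), the membrane repair gene Dysf (0.95) and the fusogenic micropeptide Mymx (1.02), and the median was 0.090 (adjusted p = 0.0627). Of 20 satellite cell and myoblast identity genes 5 rose and 1 fell (5 and 3 over the list alone, 5 and 4 with the block). The rises were in the dystroglycan gene Dag1 (1.33), the integrin Itga7 (1.00), the cadherin Cdh15 (0.91), Cd82 (0.82) and Ncam1 (0.53) and the fall in the chemokine receptor Cxcr4 (-1.07), with a median of 0.091 (adjusted p = 0.127).

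Immediate early genes passed camera with a median below 0 (25 measured, 5 fell and 1 rose, 9 and 2 over the list alone and with the block, median -0.14, adjusted p = 0.0251, and adjusted p = 0.374 with an estimated correlation). The nuclear receptor Nr4a2 fell by 1.32, Spry2 by 0.89, Ier3 by 0.64, Klf10 by 0.57 and Myc by 0.62, while Egr3 rose by 0.72. Without control replicate 2 or GREM1 replicate 3 the list had adjusted p = 0.0651 and 0.205. Unfolded protein response genes had a median of 0.18 (22 measured, 1 rose, 2 over the list alone, 3 with the block, adjusted p = 8.19e-04, and adjusted p = 0.374 with an estimated correlation), and the member that rose was Herpud1 (0.91 ± 0.11). They did not pass fry (adjusted p = 0.0621). Their median was 0.10 without control replicate 1. Against the same controls their median with BMP4 was 0.12, so the list moved the same way with ligand and antagonist. Between BMP4 and GREM1 the median was -0.059 and the list did not pass camera (adjusted p = 0.276). TGF-beta target genes had a median of -0.0090 (adjusted p = 0.839), yet 3 of 18 rose (4 rose and 2 fell over the list alone, and 3 rose and 3 fell with the block): Acta2 (1.25) and Tagln (0.80), smooth muscle proteins that early muscle cells also make, and Thbs1 (0.48). Each of these lost the call whichever GREM1 array was left out, and Tagln and Thbs1 also whichever control was (highest adjusted p = 0.118 over the alternatives).

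Markers of other cell types were tested as lists. The medians after GREM1 and after BMP4 were -0.020 and -0.037 for fibro-adipogenic progenitor and fibroblast markers (14 measured), 0.029 and -0.065 for endothelial markers (10), 0.024 and -0.0027 for macrophage and leukocyte markers (12) and -0.015 and -0.13 for Schwann cell and tendon markers (8), and none passed camera (adjusted p between 0.133 and 0.996). Pdgfra, Dcn and Lum, abundant in fibroblasts, lay below the filter, at 3.58, 2.86 and 3.23 in the controls. After GREM1 the matrix protease Mmp2 fell by 0.45, the one fibroblast marker past the test (3 over the list alone, 4 with the block), and Cxcl12 and Col3a1, at -0.88 and -0.52 (adjusted p = 0.0898 and 0.189, or 9.73e-04 and 0.00774 with the block). Among leukocyte markers Laptm5 rose by 1.14 and Cd14 fell by 0.92 (the same 1 and 1 over the list alone). Pericyte and smooth muscle markers had a median of 0.21 after GREM1 (12 measured, adjusted p = 0.0508, 0.0228 with the block, adjusted p = 0.232 with the block and an estimated correlation, and adjusted p = 0.0187 in fry), and Acta2 and Tagln were the 2 that rose (6 rose and 2 fell over the list alone, 6 and 1 with the block). After BMP4 the median was 0.025.

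The lists that follow did not pass camera against control without the block. Among 20 Notch pathway genes, GREM1 lowered Lfng (-1.02) and Hey1 and Hes1 and raised Notch1 (0.52) and Dtx4 (0.56), 3 falls and 2 rises in all (3 and 3 over the list alone), with medians of 0.0057 after GREM1 and -0.021 after BMP4. Among 18 Wnt target genes 2 rose, Lef1 (0.60) and Ccn4 (0.43), and 2 fell, Sfrp2 (-1.03) and Myc (3 and 2 over the list alone), with medians of -0.022 and -0.12. Of 11 osteoblast genes Sp7 alone passed, in both comparisons (over the list alone 1 after GREM1 and 2 after BMP4), with medians of -0.025 and -0.060. Pparg, the regulator of fat cell formation, fell by 1.22 and was the one of 16 adipogenic genes past the test (2 over the list alone and with the block), with medians of -0.092 and -0.025. The prostaglandin gene Ptgs2 and the inhibitor Nfkbia fell by 1.16 and 0.62, and Tnfaip3 rose by 0.72, among 19 NF-kB and inflammatory genes (2 and 1 over the list alone), whose medians were 0.011 and -0.0059. The atrophy ubiquitin ligase Fbxo32 rose by 0.82, the one of 20 muscle atrophy genes to pass (1 over the list alone, 2 with the block), with medians of 0.13 after GREM1 (adjusted p = 0.0508, 0.0255 with the block, and adjusted p = 0.232 with the block and an estimated correlation) and 0.062 after BMP4. Versican, Vcan, fell by 0.80 and with Mmp2 made 2 falls among 38 matrix and adhesion genes (3 over the list alone, and 5 rises with 5 falls with the block). Their medians were -0.0086 and 0.10. Rps16 fell by 1.09 among 24 ribosomal protein genes (1 over the list alone, and 1 rise with 2 falls with the block), with medians of -0.15 and 0.051. P4ha1, a collagen prolyl hydroxylase subunit, rose by 0.52 among 21 hypoxia and glycolysis genes (1 rise and 1 fall over the list alone and with the block). Of 13 cartilage, 16 interferon-stimulated, 18 p53 target and 35 oxidative phosphorylation genes 0 passed after GREM1 in limma (2, 2, 3 and 3 at an unadjusted p under 0.05, and 1 p53 target fell over the list alone). Medians after GREM1 and BMP4 were 0.00034 and -0.049 for cartilage genes, 0.0093 and -0.029 for interferon-stimulated genes, 0.031 and 0.069 for hypoxia and glycolysis genes, 0.074 and 0.041 for p53 target genes and 0.021 and 0.044 for oxidative phosphorylation genes. After BMP4 they were -0.019 for BMP receptors and SMADs, 0.077 for identity genes, 0.063 for fusion genes and 0.027 for immediate early genes. With BMP4 the genes past the test in these lists were Sp7, Ptgs2 and, among p53 targets, Btg2. Over the list alone 2 rose and 2 fell among Notch genes, 1 and 3 among Wnt targets, 2 and 1 among identity genes, 2 rose among pericyte markers and 1 among BMP receptors, and 1 fell in each of the adipogenic, Schwann and tendon, atrophy and matrix lists. With the block 2 identity genes, 1 BMP ligand or antagonist, 1 Notch gene and 1 fibroblast marker were higher and 1 adipogenic gene lower after BMP4, and 1 cartilage gene and 2 Schwann or tendon markers were higher and 1 p53 target lower after GREM1. Median and mean differed in sign after BMP4 for Notch, osteoblast, fibroblast, NF-kB, atrophy and ribosomal genes, and after GREM1 for TGF-beta targets, Notch, cartilage, endothelial, Schwann and NF-kB genes. For matrix genes after GREM1 camera pointed up where the median and mean were below 0.

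**Figure D2:**
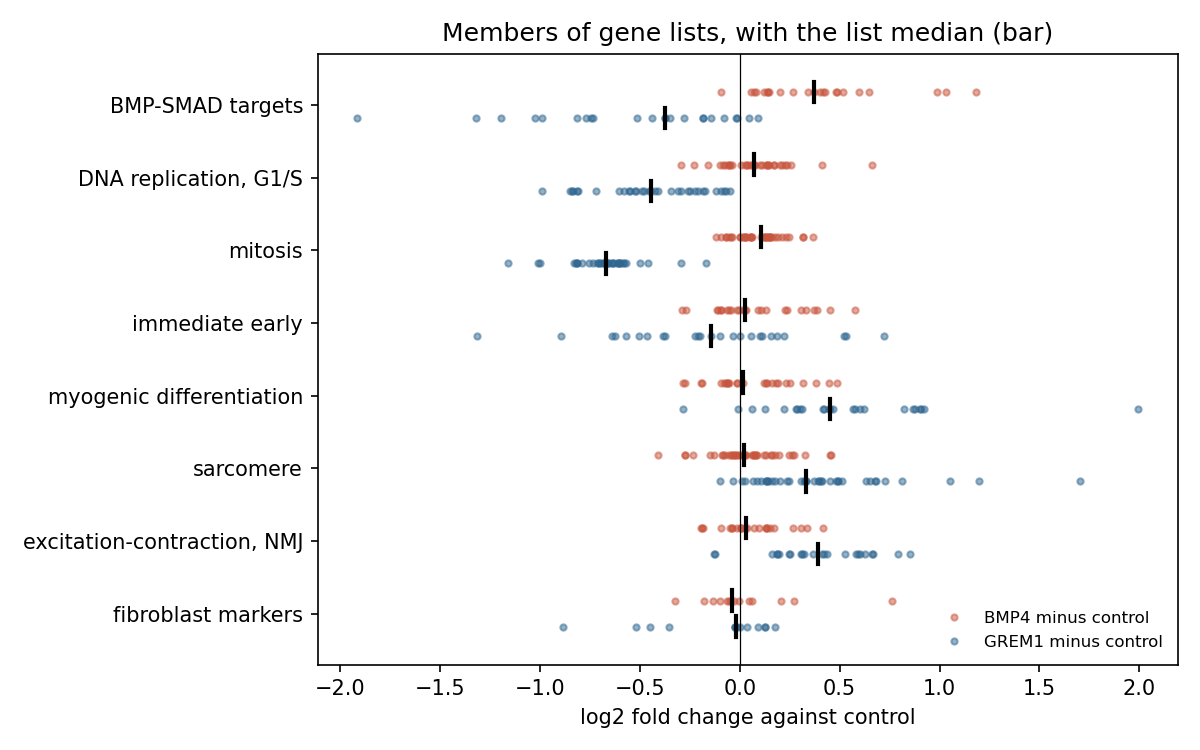
Log2 fold change against control of the single members of 8 gene lists after BMP4 (red) and GREM1 (blue); each point is a gene and the black bar the list median. BMP-SMAD targets have medians of 0.37 after BMP4 and -0.37 after GREM1, mitosis genes 0.11 and -0.67.

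The direct comparison of BMP4 with GREM1 sets the added ligand against the added antagonist. Sp7 was higher with BMP4 by 4.56 ± 0.10 (23.5-fold, adjusted p = 2.16e-08) and Fabp7 by 3.99 ± 0.11 (15.9-fold, adjusted p = 1.90e-07), followed by Sct (3.92), Selp (3.70), Kctd12 (3.46), Lgr6 (3.11), Car8 (2.72), the secreted protein Cthrc1 (2.63), Cdhr5 (2.45) and Ptgs2 (2.43). Msln differed by -2.77 ± 0.16 and Cdkn1c by -2.27 ± 0.24, lower with BMP4, as were Spry1 (-2.22), Ctrb1 (-2.14), Cyria (-2.11), Asb2 (-2.04), Dnase1l3 (-1.99), Ckm (-1.98), Pde2a (-1.98) and the guanylate-binding protein Gbp8 (-1.84). In all, 1106 genes passed, 621 higher and 485 lower with BMP4, and 258 differed at least 2-fold. With arrays centred on their medians, 550 genes were higher and 547 lower. Of the 1106 genes, 1105 had arrays that did not overlap between the groups, as did 24.5% of tested genes against 10% by chance. The count was 692 and 686 without BMP4 replicates 2 and 3, and 560 and 595 without GREM1 replicates 1 and 2. Of the 46 genes named in the text that passed in this comparison, 38 kept the call under every alternative. The call was lost by 1 and 2 without control replicates 1 and 2, by 3, 6 and 4 without BMP4 replicates 1, 2 and 3 and by 7, 8 and 3 without GREM1 replicates 1, 2 and 3. Those that lost it whichever GREM1 array was left out were Bmper, Chrnd and Nog, and whichever BMP4 array was left out Bmper and Nbl1.

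BMP-SMAD target genes were higher with BMP4 than with GREM1 in 16 of 23 members (18 over the list alone), with a median of 0.74, and this list alone held with both settings of camera (adjusted p = 4.30e-18, and adjusted p = 0.0327 with an estimated correlation), though not with the block and an estimated correlation together (adjusted p = 0.0540). Prrx2 differed by 2.26 ± 0.092, Smad6 by 2.23 ± 0.18, Smad7 by 2.21 ± 0.13, Id1 by 1.84 ± 0.21 and Id3 by 1.80 ± 0.41 (adjusted p = 0.0311, the largest of these, and 0.0889, 0.115, 0.126 and 0.110 without BMP4 replicate 2 or 3 or GREM1 replicate 1 or 2). Of 24 BMP ligands and antagonists 5 were higher and 1 lower (7 and 2 over the list alone), with a median of 0.20. They were Crim1 (1.62), Fstl1 (1.18), Grem1 (0.83), Nog (0.77), Bmper (0.66) and, lower, Nbl1 (-0.33). This list had adjusted p = 0.274 and 0.120 without BMP4 replicate 1 or GREM1 replicate 3, and immediate early genes 0.0511 without the latter (median 0.041).

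Mitosis genes were higher with BMP4 than with GREM1 in 16 of 37 members (35 over the list alone, median 0.76), replication genes in 11 of 33 (21 over the list alone, median 0.49), and immediate early genes in 7 with 1 lower of 25 (11 and 2 over the list alone, median 0.11). Kif20b differed by 0.97 ± 0.15 and the ribonucleotide reductase subunit Rrm2 by 1.51 ± 0.20. Differentiation factors were lower in 8 of 25 (9 over the list alone, median -0.38), sarcomere genes in 3 of 40 (3 over the list alone, median -0.33) and excitation-contraction genes in 3 of 24 (8 over the list alone, median -0.30). Without BMP4 replicate 3 the median was -0.20 for differentiation factors and -0.081 for sarcomere genes (adjusted p = 0.0475). The sarcomere genes were Ckm, Myh4 (-0.90) and Unc45b (-1.13), and the others Atp2a1 (-0.95), Chrng (-0.60) and Chrnd (-0.58). These 6 lists and the BMP ligands passed camera (adjusted p from 1.14e-20 to 0.0335), with adjusted p from 0.451 to 0.628 with an estimated correlation, and the sarcomere and excitation-contraction genes did not pass fry (adjusted p = 0.194 and 0.107). The other 24 lists did not pass camera (adjusted p between 0.0567 and 0.977). In them Lfng (1.67), Pparg (1.46) and Cxcr4 (1.72 ± 0.14) were higher and Lef1 (-1.08), Laptm5 (-1.54) and Fbxo32 (-1.48) lower, while Myod1 (0.15), Myog (-0.59) and Pax7 (0.36) did not pass.

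**Figure D3:**
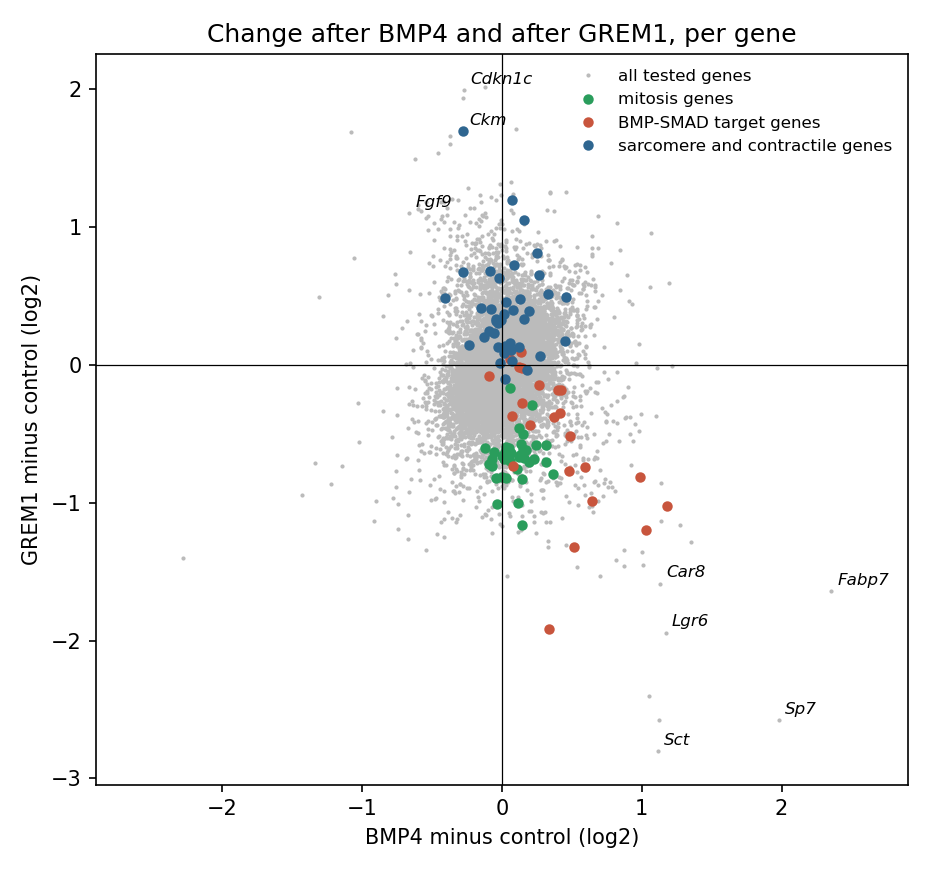
Log2 change after BMP4 (horizontal) against that after GREM1 (vertical), each against the same 3 controls, for 17141 tested genes (grey), with mitosis genes in green, BMP-SMAD targets in red and sarcomere genes in blue. Sp7 and Fabp7 lie in the lower right quadrant, and mitosis genes lie below 0 for GREM1 and near 0 for BMP4.

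Both changes were also set against each other gene by gene, to see whether ligand and antagonist moved the same genes in opposite directions. All 16 genes that rose with BMP4 had a negative value after GREM1, with a median of -0.64, and 11 of them fell past the test: Fabp7, Car8, Il13ra1, Smad7, Ptgs2, Vegfc, Adgrg3, Fam135a, Whrn, Sp7 and Lgr6. Independent lists would share 0.354 genes. Of the 4 genes that fell with BMP4, Fgf9, Itga3 and Trp53i11 rose after GREM1, where independent lists would share 0.0831, and 0 genes were called in the same direction in both. But Fgf9, Itga3 and Trp53i11 each lost the BMP4 call whichever control or BMP4 array was left out, and 0 genes were then lower with BMP4. Unchanged groups simulated against shared controls gave at most 1 gene called in both. Those simulations hold no changed gene, so they do not show how many calls unrelated responses would share. In the other direction, genes outside the BMP-SMAD targets were called for GREM1 without control replicate 1, 2 or 3 and measured from that control, since shared controls pull both values the same way, and 64.7%, 74.0% and 58.8% of them had a BMP4 value of the opposite sign. Where replicate numbers pair the arrays, leaving out 1 control pulls the BMP4 value against the sign of the GREM1 call. No share for unchanged groups was computed, so these shares do not decide the question. With all controls, 57.6% of the genes that rose and 52.2% of those that fell after GREM1 had a BMP4 value of the opposite sign. Across the 17141 genes, which are not independent replicates, Pearson's r was 0.125 and Spearman's rho 0.284, below the 0.502 and 0.464 simulated for unchanged groups with the same controls, and 62.7% of genes had the same sign against 66.7% simulated. The simulation holds no change in either group and draws each gene independently. Changes after GREM1 that are unrelated to BMP4 would lower r, rho and the same-sign share too, so these measures cannot show opposite directions. The covariance was 0.0065, against 0.0122 simulated with the spread within groups and 0.0083 with the spread left after the replicate block. When each array was left out, the covariance was lowest at 0.0018 without BMP4 replicate 1 and highest at 0.0229 without control replicate 2. Simulated values for these smaller sets were not computed. Pearson's r was 0.0742, 0.336 and 0.238 without control replicates 1, 2 and 3, 0.0302, 0.0665 and 0.257 without BMP4 replicates 1, 2 and 3, and 0.155, 0.121 and 0.0899 without GREM1 replicates 1, 2 and 3.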

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

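The tests of BMP4 activity, of a mirrored response, of fibroblast-like and osteoblast-like cells and of the Sp7 probe set were chosen only after the result was seen.

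Probe sets with no gene name here were not part of the comparisons and also responded. Of 958 such probe sets 713 passed the filter. Between BMP4 and control 1 passed the test, lower with BMP4, between GREM1 and control 28 passed, 13 higher and 15 lower, and between BMP4 and GREM1 39 passed, 21 higher and 18 lower. These are shares of 0.140%, 3.93% and 5.47%, against 0.117%, 4.14% and 6.29% of the named genes. What these probe sets measure was not tested.

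The first pattern weighed is the gap between 735 genes past the test with GREM1 and 20 with BMP4 against the same controls. A single array was argued against, since the ratio of the BMP4 count to the GREM1 count was at most 0.0490 when each array was left out. A mirror of the response was examined outside the BMP-SMAD targets, in genes called for GREM1 without 1 control and measured from that control. The median BMP4 effect in the opposite direction was at most 0.242 of the median GREM1 effect (0.0965 at the lowest). With 1 SD added it stayed below that effect, which argues against a mirror of equal size only. The same GREM1 arrays chose the genes and gave their effect, which raises that effect, and weakly active BMP4 would also lower the ratio. A smaller mirror stays open, and the 58.8% to 74.0% of these genes that went opposite ways do not decide it. Weak activity of the added BMP4 stays open. The median rise of BMP-SMAD targets was 0.990 of the size of their median fall after GREM1 (0.770 to 0.980 without each array). But the ratio of the means was 0.732 and the SD of the rises was 0.33. Over all genes 1 target rose with BMP4 where 8 fell with GREM1, but that adjustment is stricter where fewer genes changed. Over the list alone 10 rose with BMP4 and 12 fell with GREM1. At an unadjusted p under 0.05 in limma these counts were 12 and 12. Also open, as untested, is whether GREM1 blocks ligands other than BMP4, or whether BMP signalling already present left little room for a rise.

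The second pattern is the negative median of mitosis genes, -0.67, beside the positive medians of muscle differentiation genes after GREM1. The median of the mitosis genes was -0.76 without control replicate 1, the array farthest from the others, which for these genes argues against that array. It was -0.68 after quantile normalization once more. RMA had already normalized between arrays, and array medians over the tested genes lay between 6.04 and 6.09. A second normalization could therefore change little, so it is a weak test of a residual difference in array scale. The lowest medians over all alternatives were 0.343 for differentiation factors, 0.212 for sarcomere genes and 0.275 for excitation-contraction genes. For mitosis and replication genes the medians smallest in size were -0.508 and -0.338. A loss of fibroblast-like cells as large as the fall of the mitosis genes was argued against by their 14 measured markers. Their median was -0.020 (-0.33 to 0.29 within 1 SD of the markers), and 5 of them also stand in another list. Dcn and Lum, abundant in fibroblasts, lay below the filter in all groups. A smaller loss stays open. Mmp2 fell by 0.45, and Cxcl12 and Col3a1, at -0.88 and -0.52, passed with the block, where 4 markers were lower and 0 higher. Col1a1, at 5.23 in the controls, lay not far above the filter, where a fall could hardly show. A response of the cells to GREM1 stays open, and whether fewer cells divided or each cell made less of these transcripts was not tested.

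The third pattern is Sp7, which rose with BMP4 and fell with GREM1, 4.56 apart. Osteoblast-like cells would bring the other osteoblast genes with them, but the other 10 measured had a median difference of -0.011 (-0.20 to 0.18 within 1 SD), with 1 of the 11 in another list, and Bglap and Alpl, at 5.12 and 4.37 in the controls, differed by -0.39 and -0.12. Apart from Sparc, at 11.3, these 10 lay at 3.91 to 5.25 in the controls, not far above the filter. A fall with GREM1 could hardly show in such genes, and 11 of the 17 list genes named on the array were measured. A small share of osteoblast-like cells therefore stays open. Sp7 has 1 probe set in the table, so a change of Sp7 and of another transcript that this probe set reads cannot be told apart. A response of Sp7 itself to the treatments stays open, as untested.

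Other splits of the arrays of each comparison were too few, at 10, for a share under 0.05. In each comparison 1 split, the real one, gave as many genes past the threshold. The real splits gave 20, 735 and 1106 genes and the highest other split 0 in every comparison. At an unadjusted p under 0.05 the real splits gave 1375, 3421 and 3324 genes, and the highest others 2321, 1463 and 1578. For BMP4 and control, the split of control replicates 1 and 2 with BMP4 replicate 1 from the rest gave the 2321, above the real split. It parts 1 pair of equal number where the real split parts 3, so a structure that follows the replicate number may add to it. The other splits that part 1 pair gave 401 to 1375 genes, so parting 1 pair does not by itself account for the 2321. Among the 4 splits that part 3 pairs, the highest other gave 445 against 1375 for BMP4 and control, and 456 against 3421 for GREM1 and control, and 0 genes passed in either. With the replicate number as a block the real comparisons gave 65 and 1985 genes.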

How the results depend on the processing

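The block and an estimated correlation together were chosen only after the result was seen, after seeing the data. With the replicate block 65, 1985 and 2192 genes passed for BMP4 and control, GREM1 and control, and BMP4 and GREM1, against 20, 735 and 1106. With only the groups compared 5 and 437 passed for BMP4 and for GREM1 against control, where fewer arrays leave fewer degrees of freedom. Array weights gave 68 genes for BMP4 and control and 1768 for BMP4 and GREM1, and the stricter filter 31 for BMP4 and control. Leaving out each array in turn gave 2 to 17, 245 to 898 and 560 to 1155 genes. The other alternatives kept the 3 counts within 1.5 times their value. With an estimated correlation 0, 0 and 1 lists passed camera, against 4, 8 and 8, while 4, 2 and 3 had an unadjusted p under 0.05, and fry called 4, 6 and 13, of which 2, 3 and 6 had passed camera. Those that fry called and camera did not were Wnt targets and osteoblast genes for BMP4 and control, and cell cycle inhibitors, osteoblast genes and pericyte markers for GREM1 and control. For BMP4 and GREM1 they were BMP receptors, Wnt targets, osteoblast genes, leukocyte and Schwann cell markers, NF-kB genes and muscle atrophy genes. With the block and an estimated correlation together 0, 0 and 0 lists passed. For BMP4 and control 2 lists passed after quantile normalization once more, where the cell cycle inhibitor and unfolded protein response lists lost the call. With the stricter filter 2 passed, 1 of them pointing down and not called before. There the TGF-beta, cell cycle inhibitor and unfolded protein response lists lost the call. Leaving out an array gave 1 to 9, 8 to 11 and 8 to 10 lists. For BMP4 and control these were 1 without control replicate 1, 7 without control replicate 3 and 9, 8 and 9 without BMP4 replicates 1, 2 and 3. The BMP-SMAD targets kept their call against control under every alternative but the estimated correlation, alone or with the block, and between BMP4 and GREM1 under every one but both together (adjusted p = 0.0540). Pearson's r between the changes was 0.0302 to 0.336 when arrays were left out and 0.0780 to 0.180 otherwise, against 0.125. Of the named genes, Grem1 and Pax7 after BMP4, neither past the test, changed sign. Grem1 was -0.0024 after quantile normalization once more and -0.049 to 0.18 without each array, and Pax7 was -0.0028 to 0.23 without each array. Calls against control that the block changed are given with the results for lists, and for genes whose value in that comparison is given. Between BMP4 and GREM1, where the replicate numbers did not pair the samples clearly, it added muscle atrophy genes (adjusted p = 0.0420, and 0.300 with an estimated correlation) and ribosomal protein genes (adjusted p = 0.0418, and 0.322). The cause was not tested for these changes, apart from the smaller number of arrays. Genes whose signal lay below the filter, Bmp4 among them, were compared only in the alternative without it.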

Other observations

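The genes here, and their tests, were chosen only after the result was seen.

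Of 31 genes looked up in this way, some of them also named in the comparisons, 7 rose, 12 fell and 12 did not pass after GREM1. The hyaluronan synthase Has2 fell by 1.34 (adjusted p = 0.00343) beside its antisense transcript Has2os, and was 2.21 higher with BMP4 than with GREM1. The carbonic anhydrase gene Car13 fell by 1.10 (adjusted p = 0.00217) and Car8 by 1.59. Car3 fell by 1.36 (adjusted p = 0.0261), and its adjusted p was 0.0837 and 0.0660 without control replicates 1 and 2 and 0.0708, 0.0758 and 0.0713 without GREM1 replicates 1, 2 and 3. Fgf9 rose by 1.10 (adjusted p = 5.42e-04) after GREM1, where it had fallen by 0.66 after BMP4. Its call after BMP4 was lost whichever array was left out. Spry1 rose by 1.94 and Spry2 fell by 0.89.

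Of Ifi204, Ifi203-ps, Mndal and Ifi211, 2 passed after GREM1. Ifi203-ps fell by 1.46 (adjusted p = 0.0168), with adjusted p = 0.0599 and 0.0574 without control replicates 1 and 3 and 0.0666, 0.0609 and 0.0519 without GREM1 replicates 1, 2 and 3. Mndal and Ifi211 did not pass, at -1.13 and -0.62 (adjusted p = 0.200 and 0.219, or 0.0262 and 0.0134 with the replicate block). The 16 measured interferon-stimulated genes had a median of 0.0093. Related sequences can share probes, which was not tested.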
